A study of Mus musculus with 10 samples.

How the data were processed

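Gene expression was measured by RNA sequencing in muscle satellite cells, the stem cells of skeletal muscle, from 5 wild-type and 5 IL13TG mice. IL13TG mice carry a doxycycline-inducible IL-13 transgene that gives a lung disease resembling chronic obstructive pulmonary disease (COPD), per the labels' protocols. Per the same protocols, littermates of both genotypes received doxycycline in the drinking water for 2 months and were studied at 22 weeks of age. Hind leg muscle from both legs was digested, mononuclear cells were stained, and cells positive for alpha7 integrin, the product of Itga7, were collected by flow cytometry. RNA was isolated with a PicoPure kit and libraries were made with a SMART-Seq stranded kit for low input.

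The values used were counts of fragments per gene, 1 table per animal, as deposited by the authors. Per the file headers, the counts were made with featureCounts 1.6.2 in paired-end mode over exons grouped by gene identifier, on a RefSeq annotation named for mm10. Per the file headers, fragments that map to several places were counted at each of them, and no strand option was set although the kit keeps strand. Genes with near-identical copies and genes whose exons overlap a neighbour or an antisense gene can therefore share counts. Per the submitters' processing notes, the tools included FastQC 0.11.2, Trimmomatic 0.36, STAR 2.6.0c, DESeq2 1.16.1 and edgeR 3.16.5, and the build was mm9. The build was checked on the coordinates themselves. Of 23651 gene symbols matched to a GRCm38 (mm10) RefSeq table, 22255 (94.1%) had both ends within 10000 bp of that table, so coordinates are given as mm10. Gene types and exon overlaps were taken from the GENCODE annotation of the same assembly.

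Each table held 24527 genes and no row without a gene name. Total counts ranged from 11.7 to 22.4 M per library. The 45 pairs of libraries differed by a chi-square per degree of freedom of 13.0 to 168, far above sampling noise, so no library was counted as a copy of another. The sample titles are animal numbers, and the labels speak of animals, so each library was treated as 1 animal. The numbers are not shared between genotypes and give no pairs.

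The genotypes were compared with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its default minimum count of 10 and minimum total of 15, which left 16977 genes. Libraries were scaled by TMM, and genotype was the only term of a quasi-likelihood model with robust dispersion estimation. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Standard errors (SE) were derived from the log2 fold change and the F statistic, and 95% intervals from the model's degrees of freedom. Levels per library are TMM-scaled CPM, counts relative to library size, except that for Il13, the other transgene and lung genes and the sex-linked genes CPM is relative to the total count. Log2 CPM values used a prior count of 2. On simulated counts with 200 changed genes among 16619 tested, for this comparison of IL13TG against wild-type, the test recovered 3 of 50 genes changed 1.5-fold (6%), 30 of 50 changed 2-fold (60%), 49 of 50 changed 4-fold (98%) and 49 of 50 changed 8-fold (98%), with 4 false calls.

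Gene lists were fixed before the data were examined, from general knowledge of muscle stem cells, autophagy, IL-13 signalling, stresses linked to COPD and the other cells of a muscle digest. Of 35 lists, 32 were tested. The sex-linked list and the transgene and lung list were only shown per library, and none of the 13 mitochondrially encoded genes matched a gene in the tables, so that list was not tested. Lists were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, and again with the correlation estimated from the data, with fry, and with an exact two-sided permutation test of each list's mean log2 CPM per library. Members of a list were counted as past the threshold after adjustment over all genes tested and after adjustment over the list alone. Where a cell type's score was regressed out of a list's mean, the difference kept between genotypes is given in percent. Per-library checks used exact two-sided permutation tests over 252 arrangements, whose smallest possible p is 0.00794.

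Genes were named by a rule fixed before the data were examined. Il13, Pax7 and Itga7 were named whatever their result. Genes past the threshold with a mean of at least 1 CPM were to be named by size and p. Since there were none, the 16 genes with the smallest unadjusted p were named among those with at least 1 CPM and at least 4 of 5 IL13TG libraries beyond the wild-type mean on the side of the difference, leaving out predicted and pseudogene symbols. In each list up to 2 members with the smallest p were named, or up to 4 had any passed over all genes. Other genes named below passed after adjustment over their list alone or were looked up after their values were seen, as stated there.

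Alternatives fixed before the data were examined were DESeq2 size factors, upper-quartile scaling and total-count scaling inside edgeR, the edgeR likelihood ratio test, the Wald test of DESeq2 1.42.0, limma-voom with sample quality weights, other filters on low counts, dispersion estimation without the robust option, 1 surrogate variable from sva 3.50.0, the mature myofibre score as a covariate, removal of ribosomal RNA and haemoglobin genes, a test against a 1.2-fold change, an adjusted p threshold of 0.1, and leaving out each animal in turn. Covariates for the satellite cell and macrophage scores and the exact test of list means were added after the data were seen. No term for sex was fitted, because the labels give no sex, Xist was present in all 10 libraries and Y-linked genes had 0 to 4 counts. The comparison was also refitted on 100 splits of the 10 libraries into groups of 5, the real one included, drawn from the 126 that exist. Figures were drawn with matplotlib 3.10.9.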

Results

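The series asked how gene expression in muscle satellite cells differs between wild-type mice and mice with IL-13-induced lung disease, and its title names myogenesis and autophagy. Fragments were counted over 24527 genes in 10 libraries, 1 per animal, with 5 wild-type and 5 IL13TG animals. Total counts were 17.5 ± 5.13 M per library in wild-type and 17.6 ± 3.39 M in IL13TG (SD, n = 5 each; exact permutation p = 0.960). Between 21978 and 23146 genes had at least 1 count in a library. Rn45s, the ribosomal RNA precursor, took 4.92% to 12.5% of the counts. Totals, genes detected, the share of the most abundant genes, background and marker shares gave 20 checks per library, and none differed between the genotypes with an exact permutation p under 0.05.

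Satellite cell genes were expressed in every library, together with genes of other cells. Pax7, the transcription factor that marks satellite cells, ranged from 15.9 to 79.0 CPM, and Itga7, which encodes the sorted surface protein, from 104 to 531 CPM. Neither separated the genotypes. Pax7 averaged 35.6 ± 23.9 CPM in wild-type and 43.8 ± 22.3 CPM in IL13TG (SD, n = 5 each), a log2 fold change of 0.30 (SE 0.44), and Itga7 averaged 255 ± 179 and 308 ± 155 CPM, a log2 fold change of 0.27 (SE 0.48). Both depended on single animals, at 0.73 and 0.69 without wild-type replicate 1 and −0.01 for both without IL13TG replicate 1. Both had an adjusted p of 0.9997 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Pax7 lies on chromosome 4 (139738081 to 139832968, mm10) and Itga7 on chromosome 10 (128933813 to 128958284), where its exons overlap those of Mettl7b, so Itga7 counts may include fragments of that gene. Myod1, a regulator of myoblast commitment, ranged from 47.3 to 393 CPM and Myog, a regulator of differentiation, from 21.2 to 466 CPM. Genes of other cells were abundant too. Lyz2, a macrophage gene, ranged from 2024 to 6197 CPM, Ptprc, which encodes the leukocyte antigen CD45, from 190 to 416 CPM, the fibro-adipogenic marker Pdgfra from 78.1 to 239 CPM and the endothelial marker Pecam1 from 82.8 to 203 CPM. The first principal component held 39.4% of the variance and did not separate the genotypes (exact permutation p = 0.556).

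**Figure D1:**
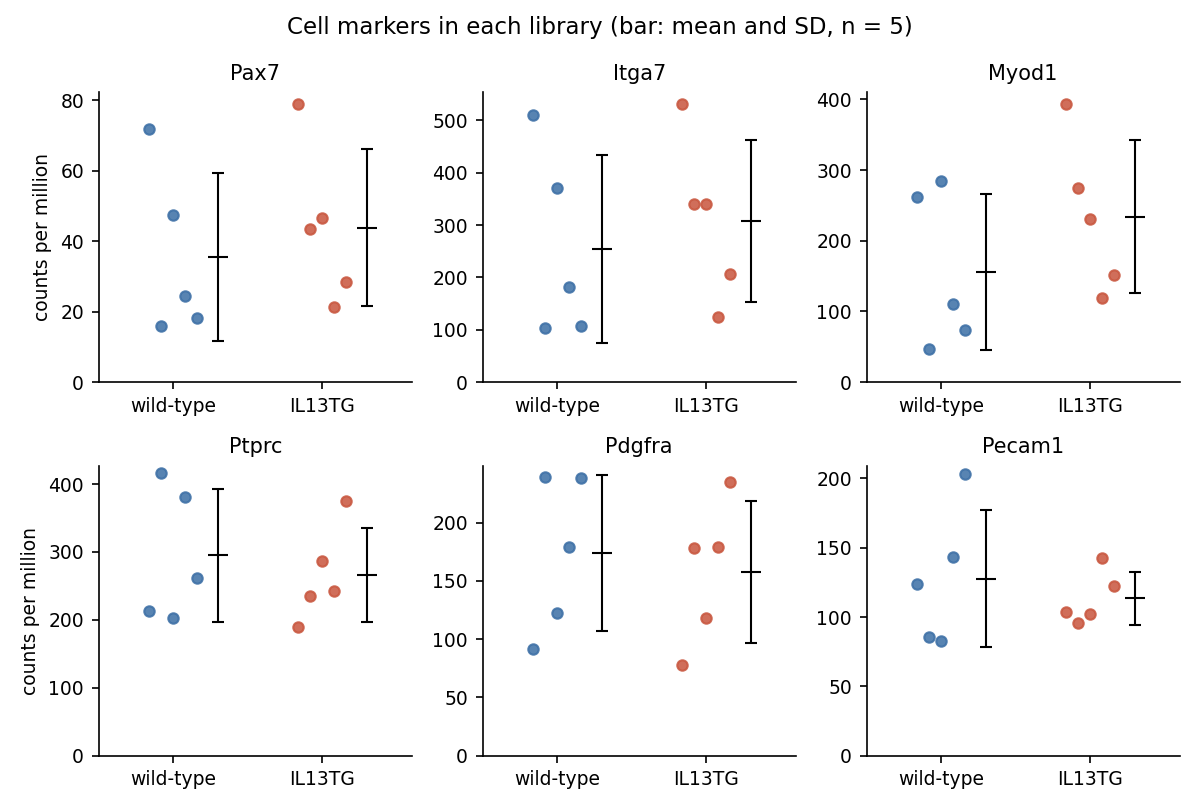
CPM of 6 cell marker genes in each library, by genotype, with points for animals and bars for the mean and SD (n = 5). Pax7 and Itga7 varied about 5-fold among the 10 libraries (from 15.9 to 79.0 and from 104 to 531 CPM), and the genotypes overlap for all 6 genes.

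Il13, the gene whose transgene defines the model, was close to background in satellite cells of both genotypes. It had between 3 and 16 counts per library. The mean was 0.352 ± 0.138 CPM in wild-type and 0.573 ± 0.325 CPM in IL13TG (SD, n = 5 each; exact permutation p = 0.238), and the gene did not pass the filter for the model. Other genes of the same fixed list, expected to be silent in these cells, lay at the same level: Il4 at 0.438 and 0.636 CPM, Il5 at 0.366 and 0.489 CPM, and Scgb1a1, an airway club cell gene, at 0.475 and 0.348 CPM in wild-type and IL13TG. The median olfactory receptor gene had 0.0448 to 0.228 CPM. Il13 lies on chromosome 11 (53631323 to 53634702, mm10). The annotation does not show whether fragments of the transgene would be counted there. Since the counts were also close to background in both genotypes, they cannot check the genotype labels. The labels give no sex. Xist, transcribed from the inactive X chromosome, was present in all 10 libraries and the Y-linked genes Kdm5d, Eif2s3y and Uty had no counts in any. Ddx3y, also Y-linked, had 4 counts in wild-type replicate 1, 1 in IL13TG replicate 4 and 0 in the other 8 libraries, and Xist was at 152 CPM in IL13TG replicate 1 against 846 to 1487 CPM in the other 9 libraries.

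Satellite cell sorts from IL13TG and wild-type mice differed in no single gene past the threshold. The genes with the lowest unadjusted p included Bnip3, a mitophagy receptor and target of hypoxia signalling, at 21.0 ± 2.19 CPM in IL13TG against 14.1 ± 1.15 CPM in wild-type (SD, n = 5 each), and Angptl4, an inhibitor of lipoprotein lipase, at 50.2 ± 4.49 against 75.5 ± 14.3 CPM. As groups, genes of tendon, extracellular matrix and the interferon response had lower values in IL13TG, and genes of glycolysis, hypoxia, ribosomal proteins and the cell cycle had slightly higher ones. None of these list differences held with an estimated correlation (lowest adjusted p = 0.349 with an estimated correlation), in fry (lowest adjusted p 0.456) or in the exact permutation test of list means (lowest adjusted p 0.660). Genes of autophagy and lysosomes were centred near 0.

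Of 16977 genes tested, 0 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and the lowest adjusted p was 0.9997. At an unadjusted p under 0.05 there were 580 genes (3.42%), 129 higher and 451 lower in IL13TG. The Wald test of DESeq2 also gave 0 genes, with 842 at an unadjusted p under 0.05 and a lowest adjusted p of 0.163, limma-voom with quality weights gave 0 with 1511, and the edgeR likelihood ratio test gave 0 with 608. The unadjusted count was 299 without wild-type replicate 2 and 1232 without wild-type replicate 3. In 78 genes (0.459%) the genotypes did not overlap, against 0.794% by chance, or 135 genes. The biological coefficient of variation was 25.4% and the median 95% interval reached 0.44 either side of the log2 fold change. The simulated comparison recovered 60% of 2-fold and 6% of 1.5-fold changes, so differences under 2-fold were often not detectable with this number and spread of animals. That simulation changed 200 genes at once, up to 8-fold, and drew genes independently. With fewer changed genes the adjustment is stricter, so these shares may be too high for the real comparison.

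Among the 16 genes with the lowest unadjusted p, 2 had higher and 14 lower values in IL13TG, and in all 16 every IL13TG library lay beyond the wild-type mean. Bnip3 (chromosome 7, 138890836 to 138909506, mm10) had a log2 fold change of 0.57 (SE 0.12) with no overlap between genotypes, and its exons overlap those of the annotated gene Gm45507. Myo7b (chromosome 18, 31959234 to 32036931), an unconventional myosin, had 0.64 (SE 0.16), at 6.01 ± 0.35 against 3.84 ± 0.69 CPM (SD, n = 5 each). Angptl4 (chromosome 17, 33774900 to 33781575) had −0.59 (SE 0.14). Tenascin C (Tnc; chromosome 4, 63959785 to 64047015) had −0.93 (SE 0.25), at 216 ± 19.02 against 412 ± 189 CPM, the elastic fibre protein gene Mfap4 −1.34 (SE 0.35), the collagen gene Col20a1 −1.03 (SE 0.25), the carboxypeptidase-like gene Cpxm2 −1.07 (SE 0.25), the protocadherin gene Dchs1 −0.64 (SE 0.17) and Adam23 −0.77 (SE 0.20). The interferon-induced gene Ifi44 (chromosome 3, 151730923 to 151749959) had −1.45 (SE 0.37) and the fast myosin-binding protein gene Mybpc2 (chromosome 7, 44501699 to 44524669) −0.84 (SE 0.22). Log2 fold changes were −0.48 for the phospholipid flippase gene Atp10a, −0.47 for Kalrn, −0.51 for the kinase gene Cdk14 and −1.13 for the potassium channel gene Kcnj15. Rnu11, a small nuclear RNA of the minor spliceosome on chromosome 4, had −1.56 (SE 0.39) at a mean of 6.97 and 2.33 CPM and lies within Gm28872 exons. Exons of Tnc, Dchs1, Cpxm2, Col20a1, Mybpc2 and Kcnj15 also overlap other annotated genes, so their counts are uncertain to that extent. The unadjusted p of the 16 genes ran from 0.000320 to 0.00283, and the adjusted p was 0.9997 for each in edgeR's quasi-likelihood test. All 16 kept their direction in the 24 alternative settings. Since they were picked by low p and by position in these same libraries, neither this nor the position of every IL13TG library is separate support.

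**Figure D2:**
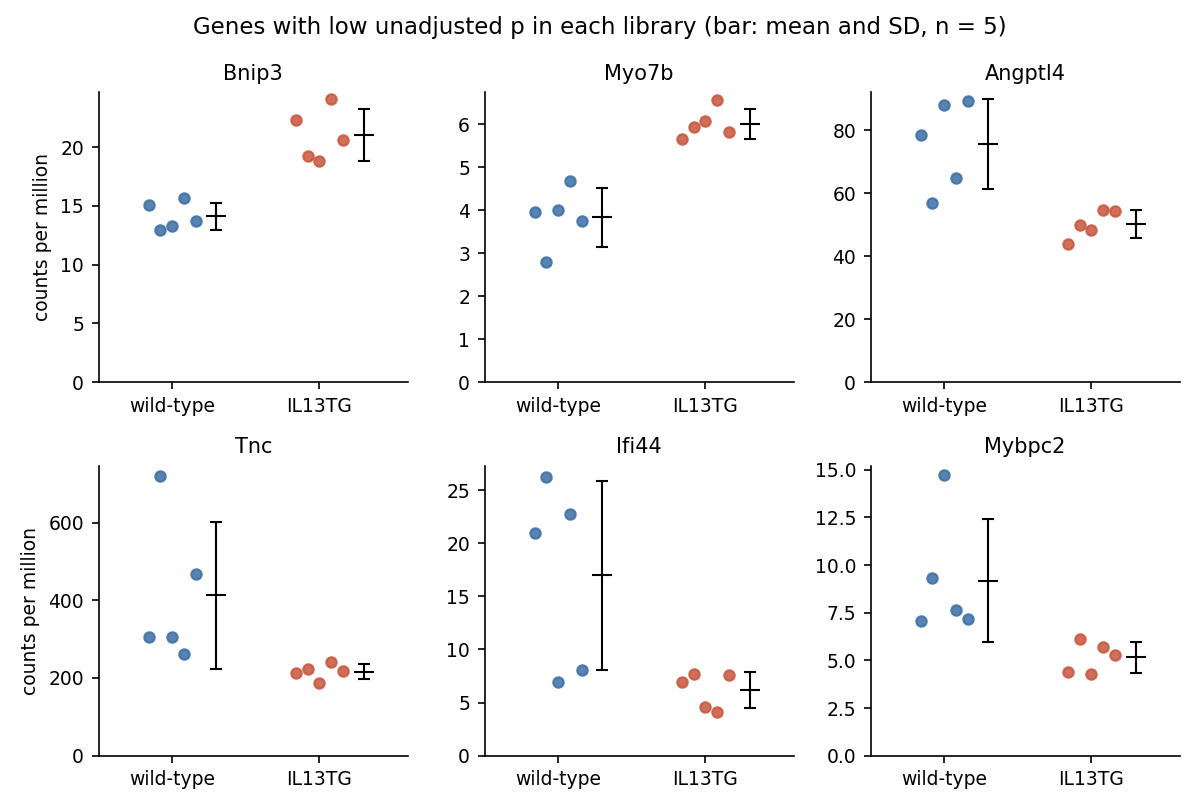
CPM of 6 of the 16 genes with the lowest unadjusted p, in each library by genotype, with points for animals and bars for the mean and SD (n = 5). Bnip3 and Myo7b lie higher and Angptl4, Tnc and Mybpc2 lower in all 5 IL13TG animals than in any wild-type animal, while Ifi44 overlaps.

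Of the 32 lists tested, 15 passed camera at an adjusted p of 0.05 with the preset correlation of 0.01, 7 with higher and 8 with lower values in IL13TG. None of the 15 held with an estimated correlation, where 4 lists had an unadjusted p under 0.05 and the lowest adjusted p was 0.349. None passed fry (lowest adjusted p 0.456, 3 lists at an unadjusted p under 0.05) or the exact permutation test of list means (lowest adjusted p 0.660, 2 lists at an unadjusted p under 0.05). In the exact test a list could pass only if several lists came near the smallest possible p of 0.00794. Over all genes, 0 of 919 list memberships passed. Adjusted over the list alone, 21 memberships in 7 lists did.

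Tendon cell genes had the most negative median of the 32 lists. All 15 genes of the tendon cell list had negative log2 fold changes, with a median of −0.86. Adjusted over the list alone, 11 fell and 4 did not pass, while 0 passed over all genes in edgeR's quasi-likelihood test. Among the 11 were Tnc, Tnmd, which encodes tenomodulin, at 28.1 against 60.4 CPM (log2 fold change −1.10, SE 0.36), Col12a1 at 243 against 422 CPM (−0.79, SE 0.24), Col11a1 (−0.86, SE 0.28), the tendon transcription factor gene Mkx (−0.62, SE 0.26) and Fmod, which encodes fibromodulin (−1.06, SE 0.38). The count adjusted over the list alone was 0 without wild-type replicate 5 or without IL13TG replicate 1, 2 or 3, 1 without wild-type replicate 2, and 3 without wild-type replicate 1. Of the 34 genes of the transforming growth factor beta and matrix list, 32 had negative log2 fold changes, with a median of −0.47, and 0 passed. Without wild-type replicate 1, 3 or 4, 7, 10 and 1 of them passed when adjusted over the list alone, and 0 over all genes in edgeR's quasi-likelihood test. Periostin (Postn) was at 338 against 682 CPM (−1.01, SE 0.31), or −0.54 without wild-type replicate 2, which was at 1443 CPM. In the fibro-adipogenic cell list 19 of 20 genes were below 0, with a median of −0.38, and 0 passed (2 adjusted over the list alone without wild-type replicate 3). Col1a1 was at 3001 against 5628 CPM (−0.91, SE 0.31, or −0.59 without wild-type replicate 2) and Col1a2 at 1950 against 3277 CPM (−0.75, SE 0.25). These 3 lists had adjusted p = 3.3e-19, 1.7e-18 and 4.8e-08 in camera with the preset correlation, and adjusted p = 0.349, 0.349 and 0.640 with an estimated correlation. Without wild-type replicate 2 the medians of the matrix and fibro-adipogenic lists were −0.30 and −0.24, and without IL13TG replicate 1 the latter was −0.25. Fibro-adipogenic transcripts took 1.85% ± 0.701 of counts in wild-type and 1.204% ± 0.357 in IL13TG (SD, n = 5 each; exact permutation p = 0.119), and tendon transcripts 0.484% ± 0.176 and 0.285% ± 0.148 (p = 0.0952).

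Interferon-response genes also had lower values in IL13TG. All 32 were below 0, with a median log2 fold change of −0.67, which ran from −0.81 to −0.43 over the alternatives and was −0.43 without wild-type replicate 2. Adjusted over the list alone, 4 fell and 28 did not pass, while 0 passed over all genes in edgeR's quasi-likelihood test. The 4 were Ifi44 at 6.18 against 17.0 CPM, Ifit1, an inhibitor of viral translation, at 36.7 against 72.9 CPM (−0.99, SE 0.28), Bst2, which encodes tetherin, at 29.2 against 50.1 CPM (−0.77, SE 0.23), and Ifi27l2a at 49.9 against 125 CPM (−1.32, SE 0.36), whose exons overlap those of Ifi27. The count adjusted over the list alone was 0 without wild-type replicate 2 or 4 or without IL13TG replicate 1, 2, 3 or 4, and 19, 24, 18 and 17 without wild-type replicate 1, 3 or 5 or IL13TG replicate 5. The list had adjusted p = 1.2e-26 in camera with the preset correlation and adjusted p = 0.349 with an estimated correlation of 0.868 between its genes. The mean log2 CPM of the list was 6.24 ± 0.60 in wild-type and 5.65 ± 0.35 in IL13TG (SD, n = 5 each; exact permutation p = 0.103). In the acute inflammation list of nuclear factor kappa B targets 22 of 31 genes were below 0, with a median of −0.06 and a camera adjusted p of 0.298, and the list passed camera only without wild-type replicate 1 when 1 animal was left out (median −0.23). Cxcl10, a chemokine that interferon also induces, had −0.70 (SE 0.31, or −0.37 without wild-type replicate 2), and Lcn2, which encodes lipocalin 2, had −0.56 (SE 0.48, or −0.37 without wild-type replicate 3, −0.30 without IL13TG replicate 1 and −0.85 without IL13TG replicate 5).

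Genes of hypoxia signalling and glycolysis had slightly higher values in IL13TG. In the hypoxia list 22 of 30 genes were above 0, with a median log2 fold change of 0.11. Adjusted over the list alone, Bnip3 rose and 29 genes did not pass, while 0 passed over all genes in edgeR's quasi-likelihood test, and Bnip3 passed within this list without any 1 of the 10 animals. The member with the next lowest p went the other way, the collagen-modifying enzyme gene Plod2 at −0.54 (SE 0.19). The list mean was 5.13 ± 0.11 in wild-type and 5.25 ± 0.04 in IL13TG on the log2 CPM scale (SD, n = 5 each; exact permutation p = 0.0238, or 0.660 after adjustment over 32 lists). In the glycolysis list 18 of 22 genes were above 0, with a median of 0.22, and 0 passed. With the fibro-adipogenic score regressed out, 46.7% of the difference in the glycolysis list's mean was kept (33.7% to 60.3% with 1 animal left out, lowest without wild-type replicate 4), and with the endothelial score 68.5% (26.2% without wild-type replicate 2 to 79.3%). For the hypoxia list the shares kept were 129% (113% to 147% with 1 animal left out) and 118% (99.6% to 140%). The glucose transporter gene Slc2a1 was at 58.1 against 47.1 CPM (0.30, SE 0.11) and Pgam1, which has annotated pseudogenes and is uncertain for that reason, at 294 against 242 CPM (0.28, SE 0.11). In camera the hypoxia and glycolysis lists had adjusted p = 0.00451 and 1.2e-05 with the preset correlation, and adjusted p = 0.349 for both with an estimated correlation. Without wild-type replicate 1 the hypoxia list did not pass camera, with a median of 0.08, and without wild-type replicate 5 the median was 0.22. Nuclear genes of oxidative phosphorylation had 40 of 50 members above 0, with a median of 0.09, and 0 passed, with Ndufa4 at −0.34 (SE 0.13) and Uqcrb at 0.27 (SE 0.12). Their camera adjusted p was 0.00600, with adjusted p = 0.937 with an estimated correlation, and the call ended without wild-type replicate 2, wild-type replicate 4 or IL13TG replicate 1 (medians 0.04, 0.03 and −0.01), while the median was 0.21, 0.14 and 0.16 without wild-type replicate 1 or 3 or IL13TG replicate 4. The glycolysis and oxidative phosphorylation means followed Itga7. They were 5.96 to 6.26 and 5.89 to 6.25 log2 CPM in the 5 libraries with the highest Itga7, which came from both genotypes. In the other 5 they were 5.72 to 5.94 and 5.58 to 5.82. In the fatty acid oxidation list 1 of 29 genes, Angptl4, fell after adjustment over the list alone and 0 over all genes in edgeR's quasi-likelihood test. It passed there only without wild-type replicate 2 or 4 when 1 animal was left out. The median of that list was −0.02, with Fabp3, which has a pseudogene, at 0.42 (SE 0.21).

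In the myogenic activation and differentiation list 25 of 29 genes were above 0, with a median log2 fold change of 0.28, and 0 passed. Myod1 was at 234 ± 108 CPM in IL13TG and 155 ± 110 CPM in wild-type (SD, n = 5 each; log2 fold change 0.59, SE 0.48) and Dll1, a Notch ligand gene, had 0.39 (SE 0.37). Myod1 was at 0.36, 0.93 and 0.32 without wild-type replicate 2, wild-type replicate 3 or IL13TG replicate 1, and Dll1 at 0.64, 0.22 and 0.16 without wild-type replicate 1, wild-type replicate 2 or IL13TG replicate 1. The list had adjusted p = 0.0347 in camera with the preset correlation and adjusted p = 0.937 with an estimated correlation. Its median was −0.20 without IL13TG replicate 1, and the camera call also ended without wild-type replicate 2, 4 or 5 or IL13TG replicate 2 (medians 0.13, 0.17, 0.08 and 0.22), and the median was 0.75, 0.46 and 0.42 without wild-type replicate 1 or IL13TG replicate 4 or 5. The satellite cell quiescence list had 17 genes above and 13 below 0, and its median of 0.04 and mean of −0.01 differed in sign. Its lowest p belonged to matrix genes, Fbln7 (−1.05, SE 0.32) and Col5a3 (−0.54, SE 0.18), and its camera adjusted p was 0.760. Without wild-type replicate 3, 3 of its genes passed when adjusted over the list alone, and 0 did with all 10 libraries. In the mature myofibre list 19 of 30 genes were below 0, with a median of −0.09. Adjusted over the list alone, Mybpc2 and Tcap, which encodes the sarcomere protein telethonin, fell, and 28 genes did not pass, while 0 passed over all genes in edgeR's quasi-likelihood test. That count was 0 without wild-type replicate 2 or 3 or without IL13TG replicate 2, 3, 4 or 5. The list had adjusted p = 0.00207 in camera with the preset correlation and adjusted p = 0.831 with an estimated correlation, and the call ended without wild-type replicate 1 or 3 or IL13TG replicate 4 or 5 (medians 0.29, −0.09, 0.06 and 0.04). Without IL13TG replicate 3 the call held while the median was 0.03, so the sign of this list's median differed from that of the test. The median was −0.18, −0.27 and −0.74 without wild-type replicate 4 or 5 or IL13TG replicate 1.

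Cell cycle genes and ribosomal protein genes had small positive values. All 30 genes of the G2 and M phase list were above 0, with a median log2 fold change of 0.15, and 0 passed. Cenpa, a centromeric histone gene, had 0.30 (SE 0.16) and the mitotic kinase gene Aurkb 0.23 (SE 0.13). Of 27 genes of the G1 and S phase list 24 were above 0, with a median of 0.17, and 0 passed. The cyclin genes Ccnd2 and Ccnd1 had −0.45 (SE 0.19) and 0.38 (SE 0.22). Both lists passed camera with the preset correlation (adjusted p = 4.2e-05 and 1.2e-04) and had adjusted p = 0.831 for both with an estimated correlation. Both calls ended without wild-type replicate 2 (medians 0.05 and 0.07, with Ccnd1 at 0.22 and Aurkb at 0.15). Without wild-type replicate 3 the medians were 0.27 and 0.28 and Ccnd1 was at 0.61, and the G2 and M phase median was 0.22, 0.08 and 0.23 without wild-type replicate 1 or IL13TG replicate 1 or 4. Both lists also followed Itga7, which was highest in wild-type replicates 1 and 3 and IL13TG replicates 1, 2 and 3. Their means were 6.29 to 6.52 and 6.09 to 6.29 log2 CPM in these 5 libraries. In the other 5 they were 5.62 to 6.09 and 5.45 to 5.99. How much of the genotype difference this structure carries was not tested. Of 83 cytosolic ribosomal protein genes 73 were above 0, with a median of 0.15 (0.22 without wild-type replicate 3), and 0 passed, with adjusted p = 5.9e-10 in camera and adjusted p = 0.640 with an estimated correlation. Rpl10, at 0.42 (SE 0.15), has annotated pseudogenes and is uncertain, and Rpl3l, the muscle-specific form, was at −0.99 (SE 0.33).

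Autophagy genes, named in the title of the series, were centred near 0. Of 49 core autophagy genes 28 were above and 21 below 0, with a median log2 fold change of 0.02 and a camera adjusted p of 0.384. When 1 animal was left out, the list passed camera only without wild-type replicate 2, with a median of 0.04. Adjusted over the list alone, Bnip3 rose (adjusted p = 0.0157) and 48 genes did not pass, while 0 passed over all genes in edgeR's quasi-likelihood test. Within this list Bnip3 did not pass without wild-type replicate 2, 3 or 5. Map1lc3a, which encodes the autophagosome protein LC3A, was at 13.9 against 17.3 CPM (−0.32, SE 0.18, or −0.15 without wild-type replicate 2). Of 45 lysosomal genes 34 were below 0, with a median of −0.04, and 0 passed. Cd63, a lysosomal tetraspanin gene with an annotated pseudogene, had 0.20 (SE 0.11) and Cln3 −0.21 (SE 0.19, or −0.10 without wild-type replicate 2 or IL13TG replicate 1 and −0.34 without IL13TG replicate 5). The list's camera adjusted p was 0.577, and it passed camera without wild-type replicate 1 or IL13TG replicate 5 with lower values (medians −0.12 and −0.11) and without IL13TG replicate 1 with higher values (median 0.06). In the atrophy and proteolysis list 20 of 28 genes were above 0, with a median of 0.09, and 0 passed, with a camera adjusted p of 0.0735. It passed without wild-type replicate 3 or IL13TG replicate 4 or 5 (medians 0.14, 0.11 and 0.11). The metallothionein genes Mt2 and Mt1 had 0.38 (SE 0.19) and 0.38 (SE 0.21, or 0.24 and 0.22 without wild-type replicate 1 or IL13TG replicate 4).

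The list of IL-4 and IL-13 signalling, which holds targets and the pathway genes Il4ra, Il13ra1 and Stat6, had slightly lower values in IL13TG. Of 31 genes 24 were below 0, with a median log2 fold change of −0.15, and 0 passed. Members went both ways. The 7 above 0 were Chil4 (0.47), Ccl24 (0.36), Clec10a (0.36), Chil3 (0.28), Retnla (0.22), Klf4 (0.09) and Mrc1 (0.07), with SE of 0.21 to 0.55. Postn, which the matrix list also holds, had the lowest p of the list, with −1.01 (−0.54 without wild-type replicate 2), and Chil1 had −0.84 (SE 0.39, or −1.37 without IL13TG replicate 4). The list had adjusted p = 0.00426 in camera with the preset correlation and adjusted p = 0.831 with an estimated correlation. The call ended without wild-type replicate 5 or IL13TG replicate 1 (median −0.04 for both). The median was −0.29, −0.09 and −0.27 without wild-type replicate 1, 2 or 3, and −0.29 and −0.23 without IL13TG replicate 4 or 5. Without IL13TG replicate 4, 1 gene passed when adjusted over the list alone.

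Stress and hormone lists did not pass camera with all 10 libraries. The glucocorticoid list had 19 of 25 genes above 0 and an adjusted p of 0.150, and Angptl4, which this list shares with fatty acid oxidation, was its only member past the threshold when adjusted over the list alone, with 0 past it over all genes in edgeR's quasi-likelihood test. Angptl4 passed there without wild-type replicate 2 or 4 or IL13TG replicate 4 or 5 and not without any other animal, while the list itself passed camera without wild-type replicate 5 or IL13TG replicate 1 (medians 0.16 and 0.21). Median log2 fold changes were 0.03 for the early response to tissue dissociation (camera adjusted p 0.586, with Egr3 at −0.42, SE 0.25, and Fosl1 at 0.62, SE 0.41), 0.03 for p53 and senescence (0.510, with Igfbp7 at −0.34, SE 0.19) and −5.3e-05 for the unfolded protein response (0.760, with Aldh18a1 at −0.24, SE 0.12, and Slc7a5 at 0.43, SE 0.28), where median and mean differed in sign. Without wild-type replicate 2 Fosl1 was at 0.37 and Slc7a5 at 0.27, without wild-type replicate 3 at 1.07 and 0.65, and without wild-type replicate 5 Igfbp7 was at −0.16. The early response list passed camera without wild-type replicate 1 with lower values (median −0.13) and without wild-type replicate 5 or IL13TG replicate 1 with higher values (0.14 and 0.18). The circadian clock list had 10 genes above and 8 below 0 and a camera adjusted p of 0.753, and its median of 0.03 and mean of −0.04 differed in sign. The clock genes Npas2 and Nr1d2 had −0.65 (SE 0.20) and 0.30 (SE 0.10).

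Markers of other cells of the digest were lower in part. All 20 endothelial genes were below 0, with a median log2 fold change of −0.32 and 0 passed. Endomucin (Emcn) had −0.69 (SE 0.24) and endoglin (Eng), whose exons overlap Fpgs, −0.46 (SE 0.19, or −0.28 without wild-type replicate 5). Of 17 lymphocyte genes 16 were below 0, with a median of −0.34 (−0.20 without wild-type replicate 4 and −0.67 without IL13TG replicate 5) and 0 passed, at levels near 1 to 2 CPM for Gzmb (−0.89, SE 0.36, or −0.44 without wild-type replicate 4) and Cd3g (−0.90, SE 0.40). Both lists passed camera with the preset correlation (adjusted p = 1.6e-06 and 1.3e-04) and had adjusted p = 0.640 for both with an estimated correlation, and the endothelial call ended without wild-type replicate 5 (median −0.13). When adjusted over the list alone, 3 endothelial genes passed without wild-type replicate 3 and 2 granulocyte genes without wild-type replicate 1. Lists for macrophages and monocytes (median −0.02), smooth muscle and pericytes (−0.01), Schwann cells (−0.10), granulocytes (−0.19), erythroid cells and platelets (0.34) and adipocytes (0.13) did not pass, with camera adjusted p of 0.749, 0.756, 0.384, 0.551, 0.622 and 0.437. The macrophage list passed without wild-type replicate 1 with lower values (median −0.17) and without wild-type replicate 2 or IL13TG replicate 1 with higher values (0.13 for both). The mural, granulocyte and adipocyte lists passed without IL13TG replicate 2 (median −0.21), wild-type replicate 1 (−0.39) and IL13TG replicate 1 (0.11). Among their members with the lowest p were Ly6c2 (−0.96, SE 0.52) and Ms4a7 (−0.26, SE 0.20) for macrophages, Tagln (−0.46, SE 0.24) and Pdgfrb (−0.50, SE 0.28) for mural cells and Cnp (−0.29, SE 0.19) and Scn7a (−0.26, SE 0.23) for Schwann cells. For the last 3 lists they included Cma1 (−0.95, SE 0.50) and Mmp9 (−0.58, SE 0.32), Slc4a1 (0.64, SE 0.50), and Scd1 (0.23, SE 0.10) and Cfd (1.75, SE 0.94). Without wild-type replicate 2 the values were −0.11 for Ms4a7, −0.27 for Pdgfrb, −0.16 for Cnp and −0.13 for Scn7a, and without wild-type replicate 3, 4 or 5 they were −0.30 for Tagln, −0.64 for Ly6c2 and −0.34 for Mmp9. Without IL13TG replicate 1, Cnp was at −0.18 and Scn7a at −0.13, and without IL13TG replicate 5, Scn7a was at −0.42 and Ms4a7 at −0.40. IL13TG replicate 3 carried the values of Slc4a1 (7.05 CPM) and Cfd (14.6 CPM, with 8.61 in IL13TG replicate 5 and 0.282 to 0.530 in the other 3 IL13TG animals), and without it their log2 fold changes were −0.00 and 0.75. Endothelial transcripts took 0.1603% ± 0.0570 of counts in wild-type and 0.1299% ± 0.0285 in IL13TG (SD, n = 5 each; exact permutation p = 0.310), and macrophage transcripts 1.14% ± 0.370 and 1.11% ± 0.342 (p = 0.889). Among the list members named here, exons of Mkx, Cxcl10, Plod2, Slc2a1, Uqcrb, Fabp3, Dll1, Ccnd2, Ccnd1, Cln3, Mt2, Fosl1, Igfbp7 and Tagln also overlap other annotated genes.

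**Figure D3:**
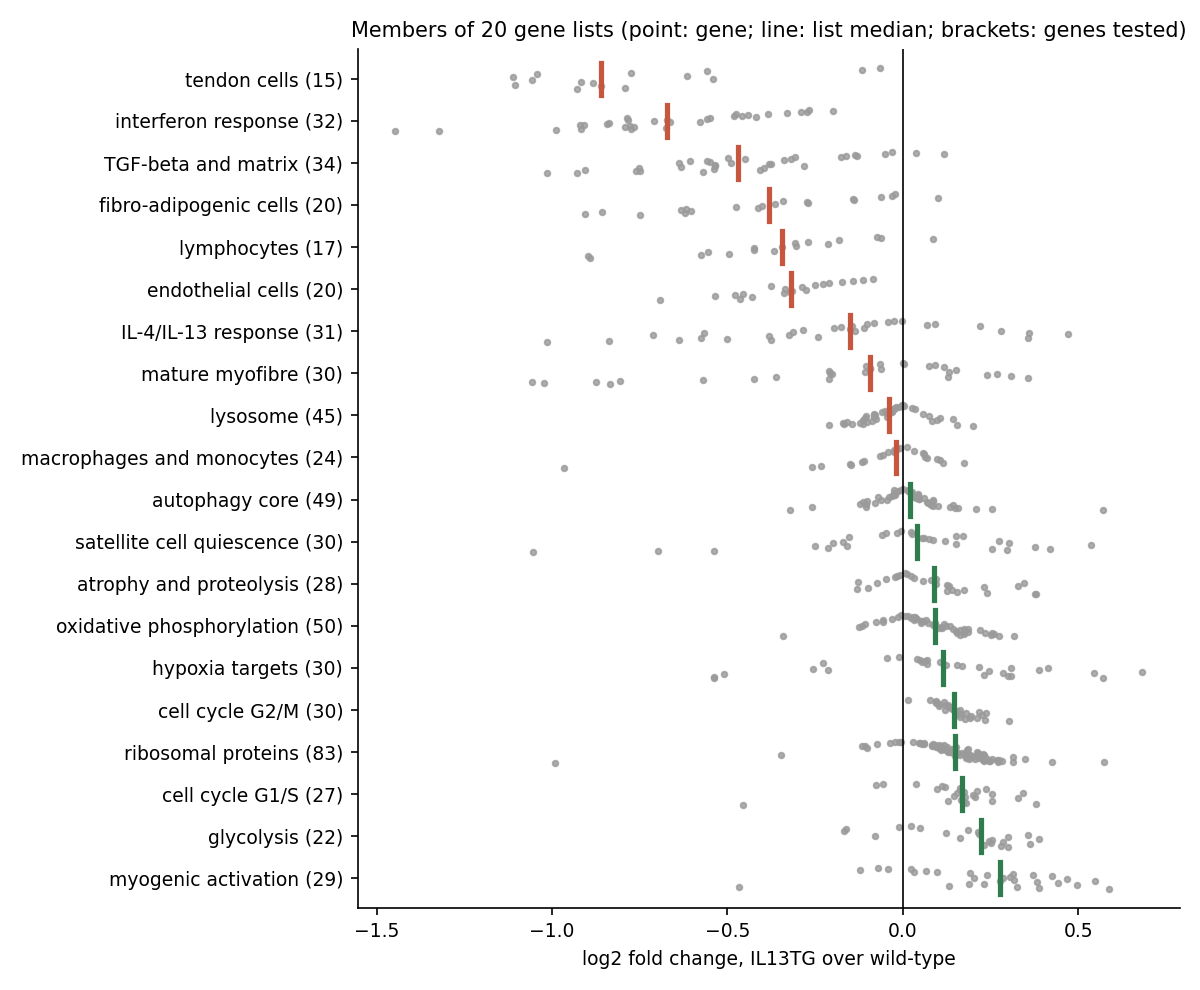
Log2 fold change of IL13TG over wild-type for the members of 20 of the 32 gene lists, the 15 that passed camera with the preset correlation among them. Points are genes and coloured lines are list medians, which run from −0.86 for tendon cells to 0.28 for myogenic activation, with autophagy at 0.02.

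**Figure D4:**
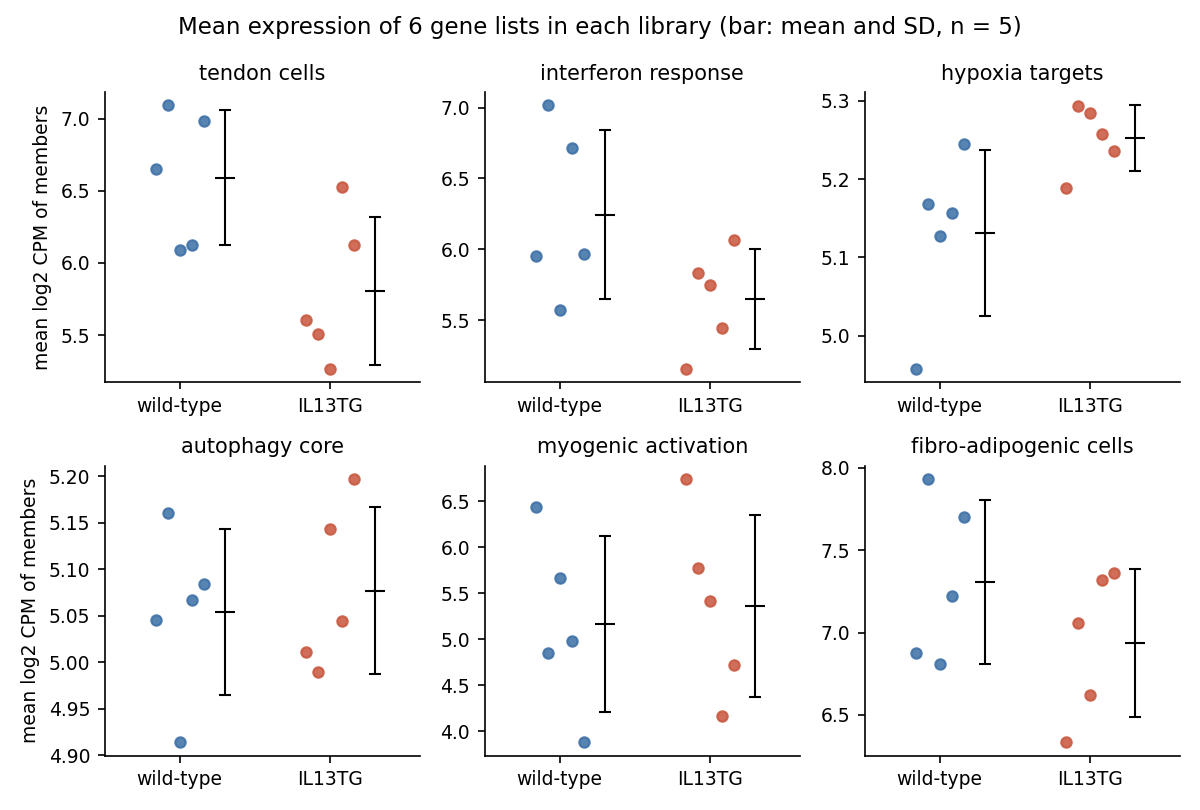
Mean log2 CPM of the members of 6 gene lists in each library, with points for animals and bars for the mean and SD (n = 5). The genotypes overlap in part for every list shown, the hypoxia list at 5.13 ± 0.11 in wild-type and 5.25 ± 0.04 in IL13TG among them.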

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

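The tests of Xist against Y-linked expression and against the composition of the sort and those of the interferon list against the fibro-adipogenic score and of the tendon and matrix lists against the endothelial score were chosen after the result was seen, and the others in this part were written down before their results were seen. Of 272 groups of 5 animals examined, 10 held an animal far from the other 4, with a gap to its nearest neighbour that took most of the range of the group. Chance alone gives about 1 in 20, or 13.6 groups. Xist in IL13TG replicate 1 was at 7.29 log2 CPM against 9.62 to 10.49 in the other 4 animals (gap 0.726 of the range). The list of acute inflammation genes in the same animal had a mean of 5.35 against 6.40 to 6.73 (0.765). In wild-type replicate 1 the mast cell protease gene Cma1 was at 0.17 against 3.41 to 4.30 log2 CPM (0.784), satellite cell transcripts took 0.464% of counts against 0.320% to 0.346% (0.819) and the second principal component was −40.8 against −3.28 to 9.68 (0.743). Periostin (Postn) in wild-type replicate 2 was at 10.49 against 8.76 to 9.21 (0.743). The remaining 4 were the macrophage gene Ms4a7 in IL13TG replicate 5 (6.19 against 5.52 to 5.70, gap 0.732), the desaturase gene Scd1 in IL13TG replicate 4 (6.33 against 6.59 to 6.65, 0.820), the adipocyte gene Cfd in wild-type replicate 3 (−0.91 against 0.75 to 1.09, 0.828) and the ribosomal protein gene Rpl10 in IL13TG replicate 3 (7.25 against 7.59 to 7.73, 0.711).

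Xist in IL13TG replicate 1 was at 152 CPM against a median of 1316 CPM in the other 9 libraries, 8.66-fold lower. Male cells are argued against by the summed Y-linked genes Ddx3y, Kdm5d, Eif2s3y and Uty at 0 CPM in this library, and the composition of the sort by wild-type replicate 1, the library closest in Itga7, where Xist was 9.39-fold higher. Loss of silencing with 2 active X chromosomes is argued against by 314 X-linked genes, whose median log2 ratio minus that of autosomal genes was 0.04 (0.0396, against −0.0729 to 0.0469 in the other libraries, SD 0.0350). A single X chromosome in most cells may remain. In this library 8 genes that escape silencing had a median log2 ratio of −0.0981 (other libraries −0.127 to 0.20, SD 0.115). Of the 8, 5 were below 0. They ran from −0.62 for Kdm6a (other libraries −0.18 to 0.24) to 0.35 for Jpx (−1.03 to 0.67). The median was on the side of the bound set against a single X chromosome but within the spread, so it decides nothing. No biological explanation was tested, since the design names none for 1 animal.

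The tendon list was lower in IL13TG by a mean of 0.78 on the log2 scale (exact permutation p = 0.0476, or 0.660 after adjustment over 32 lists), with Tnmd, Tnc and Col12a1 among its members and all 5 IL13TG animals below the wild-type mean. Fewer fibro-adipogenic cells among the sorted cells may be part of the cause. With that list's score regressed out, 63.2% of the tendon list's difference was kept (exact permutation p = 0.0952). The share was 42.6% (without wild-type replicate 1) to 75.01% when 1 animal was left out. Of the matrix list's difference 44.1% was kept (29.9% without IL13TG replicate 5 to 58.6%), and its exact permutation p went from 0.0952 to 0.0556. The matrix and fibro-adipogenic lists share Col1a1 and Col1a2, so part of that loss was built in. The score may follow collagen expression as well as cell number. The marker Pdgfra was at 158 ± 60.8 CPM in IL13TG against 174 ± 66.8 in wild-type (SD, n = 5 each), though 19 of the list's 20 genes were below 0. With the endothelial score 81.7% and 82.1% were kept (from 56.3% and 35.6%, both without wild-type replicate 2). Fewer tendon cells would lower all members alike, and 2 of 15 members had a 95% interval that left out the median, between the bounds set for and against. Neither can be told apart from an effect of genotype on matrix genes within cells, which was not tested, and although the sort on alpha7 integrin should remove both cell types, Col1a1 was at 2114 to 10143 CPM.

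The interferon list, led by Ifi44, Ifi27l2a, Ifit1 and Bst2, was lower in IL13TG by a mean of 0.60 on the log2 scale (exact permutation p = 0.103). All 5 IL13TG animals were below the wild-type mean, which wild-type replicates 2 and 4 raised, at 7.02 and 6.71. Wild-type replicates 1, 3 and 5, at 5.95, 5.57 and 5.97, lay within the IL13TG range of 5.15 to 6.07. With the macrophage score regressed out 95.4% of the difference was kept, and with the endothelial score 94.6%. With the fibro-adipogenic score it was 58.8% (exact permutation p = 0.246; 32.2% without IL13TG replicate 4 to 76.2%), so fewer fibro-adipogenic cells stay open too. The first 2 shares lie on the side of the bound set against fewer macrophages or fewer endothelial cells as the cause, but without 1 animal the shares ran from 69.8% (without wild-type replicate 1) to 128% and from 60.2% (without wild-type replicate 2) to 123%, so both may remain in part, and for these and the escape genes the condition on the spread was applied after the values were seen. An effect of genotype stays open and was not tested.

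Chance cannot be excluded for the number of genes at an unadjusted p under 0.05 or of lists past camera. The comparison used 100 of the 126 splits of the 10 libraries into 5 and 5, the real one included. For genes past the adjusted threshold it says nothing, since any of the 100 splits gives at least the real count of 0 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (580 at an unadjusted p under 0.05, and 0 in DESeq2 and in limma-voom), and the highest other split gave 4825. For genes at an unadjusted p under 0.05, 41 splits gave at least the real 580, with 7087 in the highest. For lists past camera with the preset correlation, 53 splits gave at least the real 15, with 24 in the highest. The split with 4825 genes set wild-type replicates 1 and 3 and IL13TG replicates 1, 2 and 3 against the rest. These are the 5 libraries with the highest Itga7, which points to a structure of the samples other than genotype. Only 1 other of the 100 splits gave any gene past the threshold, with 2 genes.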

How the results depend on the processing

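The covariates for the satellite cell and macrophage scores and the exact permutation test of list means were chosen after the data were seen. The number of genes past the threshold was 0 in 23 of 24 other settings, with a lowest adjusted p of 0.163 or more, as it was in edgeR's quasi-likelihood test of genotype alone (580 genes at an unadjusted p under 0.05, 299 to 2040 in the others). DESeq2 and limma-voom also gave 0, with 842 and 1511 genes at an unadjusted p under 0.05, as did the 1.2-fold test and the threshold of 0.1. The exception was the mature myofibre score as covariate, where 1 gene differed and 1 was higher: Cdkn1c, a cell cycle inhibitor gene, at a log2 fold change of 0.88 (SE 0.11, adjusted p = 0.0217 in edgeR's quasi-likelihood test) against 0.54 (SE 0.66) without the covariate. The cause was not tested.

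List members past the threshold when adjusted over the list alone numbered 21, against 0 over all genes. They were 37 with no filter, 46 in the likelihood ratio test, 47 in DESeq2, 105 with the myofibre covariate, 45 with the satellite cell covariate, 55 with the macrophage covariate, and 2 to 55 when 1 animal was left out (2 without IL13TG replicate 2 or 3, 55 without wild-type replicate 3). The cause was not tested.

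Of the 15 lists past camera with the preset correlation, 7 higher and 8 lower, 0 passed with an estimated correlation, 0 in fry, directional or mixed, and 0 in the exact permutation test, so 0 were higher and 0 lower. The estimated correlation within lists, 0.868 for interferon genes against the preset 0.01, enters the first of these. For the others the cause was not tested. With 1 animal left out, 13 to 18 lists passed, 5 to 10 higher and 6 to 12 lower, and 0 to 0 genes and per-library checks did.

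Of 864 list values under alternatives, 749 kept their side of the threshold, 82 lost it (60 of them in other tests), 26 gained it and 7 reversed. Lists that passed neither in the main test nor in the alternative are among the 749 whatever their direction. Direction here is that of the list test, and it was compared only where a list passed in at least 1 of the 2. Medians where it reversed were 0.054 for the myofibre list and −0.16 for the early dissociation list with the myofibre covariate. Without 1 animal they were −0.13 for the early dissociation list (without wild-type replicate 1), 0.13 for macrophages (without wild-type replicate 2, and 0.13 without IL13TG replicate 1), −0.20 for myogenic activation and 0.057 for lysosomes (both without IL13TG replicate 1). With 1 animal left out, medians ran from −0.20 to 0.75 for myogenic activation, −0.12 to 0.06 for lysosomes, −0.13 to 0.18 for early dissociation genes and −0.17 to 0.13 for macrophages. The median itself changed sign in 66 of the 864 values, 58 of them in lists without a call. The other 8 were in 3 called lists: myogenic activation as above, oxidative phosphorylation without IL13TG replicate 1 (−0.01), and the myofibre list with the covariate, with 1 surrogate variable (0.03) and without wild-type replicate 1 (0.29) or IL13TG replicate 3, 4 or 5 (0.03, 0.06 and 0.04). The cause was not tested. The named genes kept their sign in all 24 alternatives, except Pax7, Itga7 and Slc4a1 in 23 of 24. The median of all genes lay between −0.00385 and 0.0253 in all settings.

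No paired analysis was possible because the titles are animal numbers that the genotypes do not share. A term for sex was not run, since Xist was present in all 10 libraries and Y-linked genes had 0 to 4 counts. The mitochondrially encoded list was not run because 0 of its 13 genes matched. The effect of depth was not tested, as the simulation (60% of 2-fold and 6% of 1.5-fold changes found) used the observed totals.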

Other observations

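Npas2, Nr1d2 and Rnu11 were named by the rule fixed beforehand. The other genes of this paragraph and the next, and the permutations within genotype, were chosen after the values were seen. None of these genes passed over all genes in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.9997 for each). Rbm3 and Cirbp, which encode cold-inducible RNA-binding proteins, had higher values in IL13TG, Rbm3 at 324 ± 11.01 against 232 ± 56.8 CPM without overlap and Cirbp at 27.8 ± 3.90 against 20.3 ± 3.63 CPM (SD, n = 5 each). Their log2 fold changes were 0.48 (SE 0.16) and 0.45 (SE 0.15). Clock genes went both ways. Arntl, a core activator of the clock, had −0.42 (SE 0.15) and its partner gene Npas2 −0.65 (SE 0.20; −0.27 and −0.51 without wild-type replicate 2), while the repressor gene Nr1d2 had 0.30 (SE 0.10), and Nr1d1, Per1, Per2 and Clock had 0.21, 0.12, 0.08 and 0.07. Arntl and Nr1d2 did not overlap between genotypes, at 15.5 to 17.6 against 18.3 to 30.5 CPM and at 44.5 to 57.5 against 38.2 to 43.8 CPM. Over all genes, 78 (0.459%) did not overlap, fewer than the 135 (0.794%) that chance gives, so non-overlap alone carries little weight.

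Single genes of iron handling were looked up without a list or a test of the group. Slc40a1, which encodes the iron exporter ferroportin, ranged from 12.1 to 75.9 CPM in IL13TG (28.3 ± 26.9) and 8.30 to 18.5 CPM in wild-type (11.2 ± 4.11; SD, n = 5 each; log2 fold change 1.34, SE 0.47), Spic, the transcription factor of red pulp macrophages, had 1.12 (SE 0.44), Hmox1, which encodes heme oxygenase 1, 0.93 (95% interval −0.02 to 1.88), and the haemoglobin scavenger receptor gene Cd163 0.49 (−0.10 to 1.08), or 0.31 without IL13TG replicate 4. IL13TG replicate 3 had the highest Slc40a1, Spic and Hmox1 (75.9, 8.91 and 612 CPM), and without it their log2 fold changes were 0.54, 0.58 and 0.49. The same library had the highest share of erythroid and platelet transcripts (0.00833% against 0.00259% to 0.00515% in the other 9). Gpr34, a receptor gene of tissue macrophages, had 0.77 (SE 0.22). The resident macrophage genes Lyve1 and Folr2 had −0.03 and −0.30. Of 4 small non-coding RNA genes looked up, Rnu11 was at −1.56 (SE 0.39), Rnu12 at −1.13 (SE 0.41) and Rmrp, the RNA of a ribosomal RNA-processing enzyme, at −1.15 (SE 0.49; 789 ± 538 against 1748 ± 767 CPM, SD, n = 5 each), while the ribonuclease P RNA gene Rpph1 had −0.25 (SE 0.27). Rnu11, Rnu12 and Rmrp were also lower in replicates 4 and 5 than in replicates 1 to 3 of the same genotype. For Rmrp these were 774 and 1081 against 2172 to 2498 CPM in wild-type. In IL13TG they were 197 and 363 against 867 to 1557 CPM. When 1 animal was left out, the log2 fold change of Rmrp ran from −1.56 to −0.90. No test of a cause was run for these genes.

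Itga7, the gene of the sorted antigen, followed the content of other cells across the 10 libraries of both genotypes. Its log2 CPM went with the myogenic activation score (Pearson r = 0.93, permutation p = 0.00063 after Benjamini-Hochberg adjustment over 6 relations; Spearman rho = 0.87, adjusted permutation p = 0.0046) and the mature myofibre score (r = 0.78, p = 0.012; rho = 0.73, p = 0.024). It went against the fibro-adipogenic score (r = −0.91, p = 0.00063; rho = −0.92, p = 0.0033), the macrophage score (r = −0.83, p = 0.0051; rho = −0.76, p = 0.021) and the early dissociation score (r = −0.82, p = 0.0015; rho = −0.88, p = 0.0046). For the endothelial score r was −0.60 (p = 0.065) and rho −0.54 (p = 0.11). Without the 2 farthest libraries, wild-type replicates 2 and 5, r was 0.97, 0.92, −0.82, −0.83, −0.83 and −0.66 in the order given. Itga7 was at 339 CPM or more in 5 libraries, 2 wild-type and 3 IL13TG, and at 206 CPM or less in the other 5. With genotype means removed and all 14400 pairings within genotype permuted exactly, r was 0.93 for myogenic activation (adjusted p = 0.00125), 0.86 for myofibre (0.00417), −0.91 for fibro-adipogenic (0.00417), −0.84 for macrophage (0.00858), −0.85 for early dissociation (0.00125) and −0.57 for endothelial scores (0.150), and on ranks within genotype 0.90, 0.80, −0.90, −0.70, −0.90 and −0.55 (adjusted permutation p = 0.00861, 0.0288, 0.00861, 0.0627, 0.00861 and 0.145). Macrophage genes were detected in all 10 libraries, with Lyz2 at 2024 to 6197 CPM and C1qa at 234 to 571 CPM, although the sort on alpha7 integrin should remove these cells.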
